A study of Mus musculus with 8 samples.

How the data were processed

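The deposited table held 8 columns, 1 per array, of intensity values that the authors computed with MAS5 and analysed with Partek, for which no versions were given. The values were on the linear scale, and the mean of each array after leaving out 2% of values at each end was 500, so arrays had been scaled before deposition. RNA had been extracted with Trizol and RNeasy, pooled per genotype and tissue, and labelled with the 3' IVT Express kit; the number of animals per pool was not given. The labels say ileum for small intestine. No raw array files were used, and the summary of probes into probe sets was not repeated.

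Of 45101 probe sets, 64 controls were left out of the tests, 34945 were assigned to 1 gene, 932 to several and 9160 to none. Genes were matched through gene identifiers for 34741 probe sets, and 0 symbols needed updating. Only probe sets with 1 gene were kept, which gave 18193 genes. Values below a floor of 64.1 (log2 6.00), the median over arrays of each array's 40th percentile, were set to the floor, and log2 was taken. For each gene the probe set with the highest mean over the 8 arrays was used. Genes above the floor in at least 2 of 8 arrays were tested, which left 14027.

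All contrasts came from 1 limma model (limma 3.58.1 in R 4.3.3) with 6 coefficients: 4 intercepts for tissue and tumour status, and 1 ACKR2 effect per tumour status shared by both tissues. With 1 array per group, the only spread available was how far the ACKR2 effect differed between the tissues. This left 2 residual degrees of freedom, to which the empirical Bayes step with a trend added 4.12 prior ones; the median standard deviation was 0.22 on the log2 scale. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. Because each pool stands for 1 measurement, standard errors and p-values describe these arrays and carry no estimate of variation between animals. The pairs of arrays that differ in 1 factor were also described alone, without p-values, by counting genes at least 1 apart on the log2 scale.

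The comparisons, the settings, the lists and the rule for naming genes were written before the data were examined. The 29 lists were ACKR2 ligands, other chemokines, chemokine receptors, mast cells, cytotoxic T and NK cells, helper and regulatory T cells, B and plasma cells, macrophages, neutrophils, the leukotriene pathway, inflammatory cytokines, the interferon response, MHC class II, Wnt targets and stem cells, proliferation, small-intestinal enterocytes, colonocytes, goblet cells, Paneth cells, enteroendocrine cells, tuft cells, smooth muscle, enteric neurons and glia, fibroblasts and matrix, endothelium, adipocytes, exocrine pancreas, red blood cells and the early stress response. Each list was tested per contrast with camera, with a preset correlation between genes of 0.01 and with an estimated correlation, and adjusted over the lists of a contrast. With the estimated correlation 0 lists passed in any contrast, at adjusted p-values of at least 0.442. For single pairs, list medians were set beside 10000 random lists of the same size and mean expression. Listed genes not analysed here because the array table did not assign a probe set to them or because of the filter include Ccl19, Mcpt9, Isg15, Tpsab1, Ifng, Foxp3, Cd4 and Il6.

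Genes were named by a fixed rule. It took Ackr2 and Apc; for each comparison up to 10 genes higher and 10 lower, ranked by the smallest difference over its pairs, among genes at least 2-fold apart in the same direction in every pair; for each tumour tissue alone the 5 highest and 5 lowest in the ACKR2 pair; up to 4 members per list; and Mcpt1, Mcpt2, Cpa3, Cd8a, Gzmb, Ltb4r1, Alox5, Axin2, Lgr5 and Ccl2 in every comparison. Xist, Eif2s3y, Kdm5d, Uty and Ddx3y, of which Ddx3y was not analysed here, were named to check sex, and the Actb and Gapdh control probe sets to check RNA quality.

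Other settings chosen beforehand were no floor, a floor at the 25th or 60th percentile, no filter, a filter on all 8 arrays, quantile normalization, median centring, the mean of all probe sets of a gene, an additive model, no trend, a threshold of 1.5 on the log2 scale, and leaving out each array in turn. Chosen after the data were seen were the tests without Xist and chromosome Y genes, without both WT arrays, without both ACKR2KO_ApcMin arrays, with 1 ACKR2 effect for all arrays, and median centring for lists.

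The procedure was also run on simulated arrays with known changes, built from the fit to these arrays. For the ACKR2 effect in tumours it recovered 50, 92, 100 and 100% of 50 genes changed by 1, 2, 3 and 4 on the log2 scale, with 7 false calls among 13827 unchanged genes. For the tumour effect in colon it recovered 42, 88, 84 and 94%, with 10 false calls. It called 20 of 20 lists that had been moved by 0.8 and 3 of 560 that had not. In all simulated arrays the ACKR2 effect was the same in both tissues, and noise had the spread per gene from the fit. The rates for genes therefore do not cover genes whose ACKR2 effect differs between the tissues. The lists were random genes with noise drawn independently for each gene, so the rates for lists do not cover lists whose genes move together. The estimated correlation was 0.503 for smooth muscle and 0.636 for Wnt targets and stem cells. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 prepared the table, tests of array measures and figures.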

Results

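Gene expression was measured on 8 Affymetrix arrays of colon and small intestine from C57BL/6 mice aged 110 days. ApcMin/+ mice carry a mutated allele of the tumour suppressor Apc and develop intestinal tumours. ACKR2, also called D6, is an atypical receptor that binds inflammatory CC chemokines and removes them. Each tissue gave 4 arrays: tissue without tumours from wild-type (WT) and ACKR2-deficient (ACKR2KO) mice, and tumours from ApcMin and from ACKR2KO_ApcMin mice. Each array held RNA pooled within 1 genotype, so every group had n = 1 array and no group had replicates. The median signal of an array ran from 85.5 to 133.1. The number of arrays limits the precision of every value. All values below a signal of 64.1 were set to it, and 14027 genes above it in at least 2 arrays were tested. A difference from a value at this floor is a lower limit of its size. Standard errors and adjusted p-values come from 1 limma model with 2 residual degrees of freedom. They measure how far the ACKR2 effect differed between the tissues, not how animals differ. Each named gene that rose or fell did so in every pair of its comparison, 2 of 2 or 4 of 4, except Ccl2 and Mcpt1 in the averaged tumour effect (3 of 4 pairs each).

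Genes that mark sex differed between the pools. Xist, the RNA of the inactive X chromosome, had a signal of 9809 in WT colon and 7807 in WT small intestine. It had 77.9 and 127 in the ACKR2KO_ApcMin tumours of colon and small intestine, and between 2818 and 4827 in the other 4 arrays. Eif2s3y, a gene of the Y chromosome, had signals of 2.92 and 2.66 in the WT arrays and between 888 and 1501 in the other 6. The Y-linked Kdm5d had 16.3 and 8.89 in the WT arrays and at least 282 elsewhere. ACKR2 genotype also moved with measures of RNA and signal. The Actb 3'/5' signal ratio averaged 1.32 in the 4 arrays with ACKR2 loss and 1.14 in the other 4 (exact two-sided permutation test, p = 0.0286, adjusted p = 0.0643 over 9 measures). Median signal averaged 92.8 and 124, with the same p-values, while the Gapdh 3'/5' ratio averaged 0.808 and 0.842 (exact two-sided p = 0.543).

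**Figure D1:**
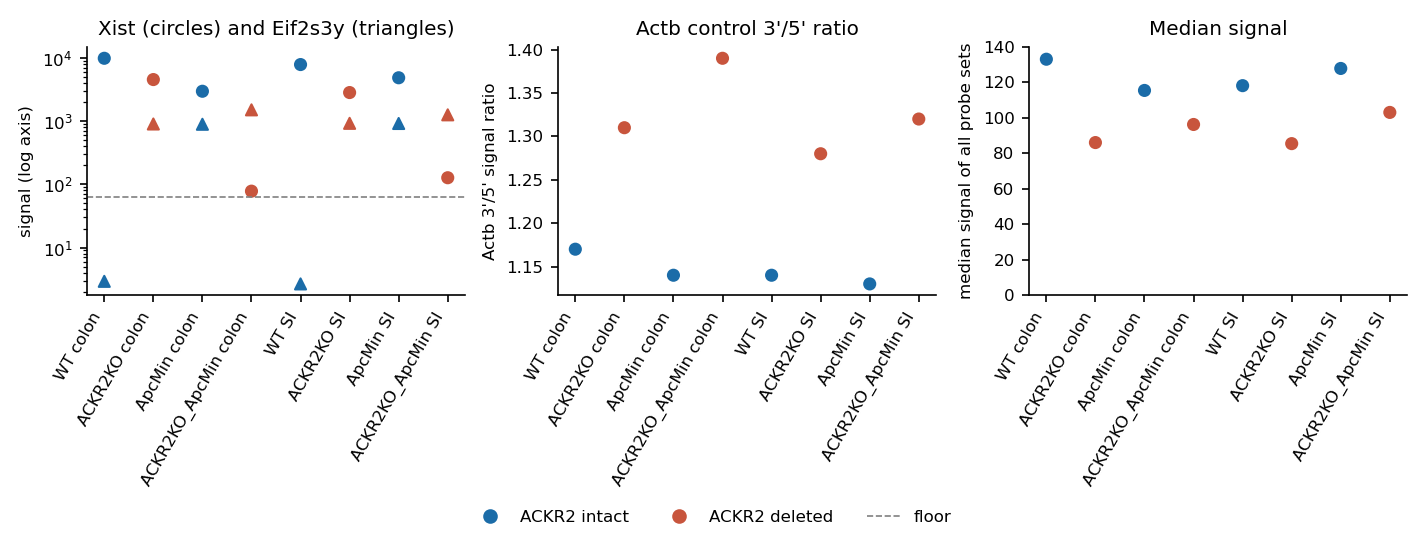
Signals of Xist and Eif2s3y on a log axis, the Actb 3'/5' signal ratio, and the median signal of all probe sets, with 1 point per array (SI, small intestine). Xist is lowest in both ACKR2KO_ApcMin arrays, Eif2s3y lies under the dashed floor of 64.1 in both WT arrays, and the Actb ratio is between 1.28 and 1.39 in the arrays with ACKR2 loss and between 1.13 and 1.17 in the others.

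The probe set chosen for Ackr2 had signals between 71.3 and 153 in all 8 arrays, with 107 and 122 in ApcMin and ACKR2KO_ApcMin colon tumours. These values lay not far above the floor of 64.1, in WT arrays too. The other Ackr2 probe sets had 22.25 to 98.6 and 1.10 to 10.5. Where the chosen probe set lies relative to the deleted part of the gene is not known, so it does not check the genotype. Apc had signals between 1163 and 1725.

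Non-tumour colon was compared with non-tumour small intestine to check the tissue labels. Markers of small-intestinal enterocytes were lower in colon for 21 of 22 measured genes, and Paneth cell genes, which belong to the antimicrobial cells of the small-intestinal crypt, for 6 of 7. The median log2 difference was -5.67 for the enterocyte list (camera adjusted p = 1.28e-22, adjusted p = 0.603 with an estimated correlation) and -7.16 for the Paneth cell list (adjusted p = 4.12e-10, 0.603 with an estimated correlation). For colon against small intestine in non-tumour tissue, 1811 genes were higher and 1176 lower. With arrays centred on their medians, which moved the median of all genes by -0.11, these counts were 1357 and 1483.

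Tumours were compared with non-tumour tissue to ask what sets tumours apart in both tissues. The sex markers moved with tumour status too, as Xist was lower and Eif2s3y higher in the tumour pool of all 4 pairs. In colon, Xist had 9809 in WT and 2954 in ApcMin, and 4522 in ACKR2KO and 77.9 in ACKR2KO_ApcMin. A part of sex in the tumour effects, averaged or within colon or small intestine, was not tested. Feedback inhibitors of Wnt signalling were among the genes that rose most in all 4 tumour pairs: Wif1 by 5.68 ± 0.21 and Notum by 5.13 ± 0.27 on the log2 scale. The amino acid transporter gene Slc38a4 rose by 4.92 ± 0.16, Wfdc18 by 5.94 ± 0.11, and Lcn2, which encodes an iron-scavenging antimicrobial protein, by 4.22 ± 0.31. Their adjusted p-values were 0.000247, 0.000595, 0.000247, 3.53e-05 and 0.0014. Ranked by the smallest difference over the 4 pairs, Onecut2, Alb, Cfi, Sox17 and Tesc completed the 10 genes that rose most. All 10 smooth muscle genes fell in the averaged tumour effect (list median -2.88, camera adjusted p = 9.03e-10, 0.523 with an estimated correlation), among them Myh11 (log2 -3.81 ± 0.43, adjusted p = 0.00409), Smtn (-3.12 ± 0.14, 0.000354), Synm (-3.90 ± 0.19, 0.000502) and Lmod1 (-2.60 ± 0.18, 0.00134). Pcp4, Trnp1, Sntg2, Ntn1, Sparcl1 and Pgm5 also fell by at least 2-fold in every pair. The stem cell gene Lgr5 rose by 2.42 ± 0.19 (adjusted p = 0.00159), the Wnt target Axin2 by 1.80 ± 0.25 (0.00698), and the chemokine gene Ccl2 by 0.94 ± 0.14 (0.00891). The mast cell protease genes Mcpt1 and Mcpt2 rose by 4.68 ± 0.65 and 4.32 ± 0.42 (adjusted p = 0.00679 and 0.00256), and Cpa3 by 2.65 ± 0.25 (0.00235). Cd8a, the co-receptor gene of cytotoxic T cells, differed by 0.75 ± 0.24 (adjusted p = 0.0676), and Gzmb, Ltb4r1 and Alox5 did not pass either, with adjusted p-values of 0.881, 0.885 and 0.392. At the 4 other probe sets of Cd8a the direction was the opposite. Averaged over both tissues, 1840 genes rose and 1669 fell. A set of 160 genes was at least 2-fold higher and 114 at least 2-fold lower in all 4 pairs, where independent lists of these sizes would share 0.331 and 0.191. Without both WT arrays the limma model called 0 genes (3442 at an unadjusted p under 0.05), as it did without both ACKR2KO_ApcMin arrays (4600) or with any single array left out (3087 to 5277).

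In colon, tumours had higher Wnt target, proliferation, antimicrobial and neutrophil genes than non-tumour colon. Of 22 measured Wnt target and stem cell genes 21 rose and 0 fell (22 and 0 adjusted over the list alone), led by the metalloproteinase gene Mmp7 (log2 7.47 ± 0.19, adjusted p = 0.000137, at least 151-fold in both pairs), Wif1 (6.34 ± 0.30), Notum (5.40 ± 0.38) and Prox1 (4.05 ± 0.47). Axin2 rose by 2.96 ± 0.36 and Lgr5 by 3.57 ± 0.27. The list median was 2.60 (camera adjusted p = 4.16e-15, adjusted p = 0.509 with an estimated correlation). Of 21 proliferation genes 20 rose and 0 fell (20 and 0 adjusted over the list alone), among them Rrm2 (2.24 ± 0.16), Birc5 (1.96 ± 0.20) and Plk1 (1.82 ± 0.22), with a median of 1.48 (adjusted p = 3.79e-12, 0.509 with an estimated correlation). Paneth cell genes rose in 5 of 7 cases (5 adjusted over the list alone). These 7 genes hold no defensin: Defa3 was left out by the filter, and Defa5, Defa17, Defa20, Defa21, Defa22 and Defa24 were not assigned a probe set. Mmp7 counts in this list and in the Wnt list. The antimicrobial lectin genes Reg3b and Reg3g rose by at least 275-fold and 178-fold in both pairs, and Itln1 by 5.75 ± 0.27. The list median was 5.75 (adjusted p = 2.37e-06, 0.509 with an estimated correlation).

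Neutrophil genes rose in 5 of 7 cases in colon tumours (6 adjusted over the list alone), with S100a9 at 4.36 ± 0.27, S100a8 at 4.34 ± 0.42 and Mmp9 at 3.02 ± 0.32. Their median was 3.02 (adjusted p = 0.000322, 0.509 with an estimated correlation). Inflammatory cytokine genes rose in 6 of 14 cases (7 adjusted over the list alone), led by Il1b (3.28 ± 0.33), Il23a (2.79 ± 0.31) and Tnf (1.68 ± 0.22), with a median of 0.80 (adjusted p = 0.000723, 0.525 with an estimated correlation). Of 17 other chemokines 9 rose and 3 fell (9 and 4 adjusted over the list alone). The neutrophil attractants Cxcl2 (4.84 ± 0.29), Cxcl5 (3.55 ± 0.37) and Cxcl1 (2.88 ± 0.28) led them, and the median was 1.10 (adjusted p = 0.0283, 0.509 with an estimated correlation). Of 11 ACKR2 ligands 4 rose and 0 fell, as they did adjusted over the list alone. Ccl2 (1.65 ± 0.20, adjusted p = 0.00538), Ccl17 (1.35 ± 0.21) and Ccl3 (1.02 ± 0.21) were among them, while the list itself did not pass (median 0.76, adjusted p = 0.0565). Among 12 mast cell genes 3 rose (3 adjusted over the list alone), namely Hdc (adjusted p = 0.00591), Mcpt2 (3.11 ± 0.59) and Cpa3 (1.40 ± 0.35), and the list did not pass (adjusted p = 0.132). Mcpt1 differed by 2.59 ± 0.91 (adjusted p = 0.0925), higher in 1 of 2 pairs.

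Markers of the muscle wall, and some markers of colonocytes and enteroendocrine cells, fell in colon tumours. All 10 smooth muscle genes fell (10 adjusted over the list alone), with Myh11 at -4.80 ± 0.61, Synm at -4.68 ± 0.27 and Des at -3.87 ± 0.35, and a median of -3.58 (adjusted p = 8.14e-09, 0.509 with an estimated correlation). Enteric neuron and glia genes fell in 6 of 10 cases (6 adjusted over the list alone), including Snap25 (-2.31 ± 0.28) and Prph (-2.02 ± 0.35), with a median of -1.36 (adjusted p = 0.000666, 0.509 with an estimated correlation). Of 15 colonocyte genes 7 fell and 2 rose (9 and 3 adjusted over the list alone). The proton pump gene Atp12a fell by 3.44 on the log2 scale, the sodium channel gene Scnn1g by 3.69 and the carbonic anhydrase gene Car4 by 2.30, and the list median was -1.69 (adjusted p = 0.0401, 0.603 with an estimated correlation). Enteroendocrine genes fell in 5 of 15 cases and rose in 1, as they did adjusted over the list alone. Chga was at -1.78 ± 0.28 and Chgb at -1.92 ± 0.36, and Nts rose by 1.23 ± 0.29. Their median was -0.50 (adjusted p = 0.0401, 0.603 with an estimated correlation). Adipocyte genes fell in 2 of 5 cases (3 adjusted over the list alone), Car3 by 5.91 and Fabp4 by 2.22 on the log2 scale, with a median of -2.22 (adjusted p = 0.0401, 0.603 with an estimated correlation). The calls of the colonocyte, enteroendocrine, adipocyte, other chemokine, and enteric neuron and glia lists held in 2, 2, 3, 4 and 5 of 6 alternative settings.

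The remaining lists did not pass in colon tumours. The camera adjusted p was 0.356 for chemokine receptors, where Ccr1 (1.22 ± 0.24) and Cx3cr1 (1.16 ± 0.24) rose, 0.144 for cytotoxic T and NK cells, and 0.606 for helper and regulatory T cells. It was 0.802 for B and plasma cells, 0.0942 for macrophages, 0.923 for the leukotriene pathway, 0.247 for the interferon response and 0.833 for MHC class II. Small-intestinal enterocyte markers reached 0.237, goblet cells 0.558, tuft cells 0.295, endothelium 0.074, exocrine pancreas 0.258, the red blood cell gene Alas2 0.647 and the early stress response 0.209. Fibroblast and matrix genes (adjusted p = 0.606) had a median of 0.03 and a mean of -0.22: Timp1 rose by 2.31 ± 0.39, and Lum and Postn were at -2.48 ± 0.20 and -2.00 ± 0.24. In all, 1552 genes rose and 1764 fell in colon tumours. Genes at least 2-fold apart in both colon pairs numbered 680 higher and 860 lower, where independent lists would share 92.4 and 146. With any single array left out, limma called 0 genes (2357 to 5231 at an unadjusted p under 0.05).

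In small intestine, tumours had higher mast cell, B cell and Wnt genes, and lower smooth muscle genes. Mast cell genes rose in 8 of 12 cases (9 higher and 1 lower adjusted over the list alone). The proteases Mcpt1 and Mcpt2 rose by 6.76 ± 0.91 and 5.53 ± 0.59 (adjusted p = 0.0189 and 0.00927), Cpa3 by 3.91 ± 0.35 (0.00635) and Fcer1a by 2.64 ± 0.21 (0.00423). Their median was 1.85 (camera adjusted p = 6.73e-07, 0.596 with an estimated correlation). B and plasma cell genes rose in 9 of 14 cases (10 adjusted over the list alone), with the B cell surface gene Ms4a1 at 4.61 ± 0.35, the complement receptor gene Cr2 at 3.38 ± 0.27 and Cd22 at 3.21 ± 0.30, and a median of 2.501 (adjusted p = 9.84e-08, 0.631 with an estimated correlation). Chemokine receptors rose in 4 of 14 cases (4 adjusted over the list alone): Cxcr4 (2.93 ± 0.24), Ccr6 (2.82 ± 0.25), Cxcr5 (2.30 ± 0.20) and Ccr7 (0.91 ± 0.17). Their median was 0.12 (adjusted p = 0.0401, 0.596 with an estimated correlation), and it was -0.04 after quantile normalization. The B cell attractant Cxcl13 rose by 3.47 ± 0.19 (adjusted p = 0.00261). It was the 1 of 17 other chemokines that rose, against 5 higher and 4 lower adjusted over the list alone, and that list did not pass (adjusted p = 0.952).

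Wnt target and stem cell genes rose in 10 of 22 cases in small-intestinal tumours (16 adjusted over the list alone), including Wif1 (5.02 ± 0.30), Notum (4.87 ± 0.38), Nkd1 (3.08 ± 0.26) and Prox1 (3.15 ± 0.47), with a median of 1.35 (adjusted p = 1.51e-10, 0.631 with an estimated correlation). Lgr5 differed by 1.27 ± 0.27 (adjusted p = 0.063; its 1 other probe set went the opposite way) and Axin2 by 0.63 ± 0.36 (0.381). No proliferation gene passed alone (6 rose adjusted over the list alone), and the list median was 0.26 (adjusted p = 0.00473, 0.773 with an estimated correlation). Helper and regulatory T cell genes had a median of 0.54 (adjusted p = 0.0366, 0.596 with an estimated correlation) with 0 of 5 passing. Other genes that rose most were Wfdc18 (7.33 ± 0.16, adjusted p = 8.06e-05), Slc38a4 (5.21 ± 0.23), the stomach gene Gkn3 (5.35 ± 0.30) and the cathepsin gene Ctse (5.08 ± 0.16). The 1 other probe set of Ctse went the opposite way.

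Smooth muscle genes fell in 7 of 10 cases in small-intestinal tumours (10 adjusted over the list alone), among them Synm (-3.12 ± 0.27), Smtn (-2.49 ± 0.20) and Lmod1 (-2.26 ± 0.25), with a median of -2.21 (adjusted p = 7.56e-12, 0.596 with an estimated correlation). Myh11 differed by -2.81 ± 0.61 (adjusted p = 0.067). The amino acid transporter gene Slc6a14 fell by 4.29 and the potassium channel subunit gene Kcnip2 by 2.30 on the log2 scale (adjusted p = 0.00709 and 0.00509). Several other lists passed with a lower median. They were the interferon response (-0.44, adjusted p = 0.0143, 0.596 with an estimated correlation), enterocytes (-0.37, 0.00473, 0.773 with an estimated correlation), enteric neurons and glia (-0.65, 0.00394, 0.596 with an estimated correlation) and adipocytes (-1.97, 0.00435, 0.763 with an estimated correlation). No gene of these lists passed over all genes, and adjusted over the list alone, 3, 0, 2 and 4 fell. The enterocyte fall came from 1 pair, with a median of -0.79 for ApcMin minus WT and 0.04 for ACKR2KO_ApcMin minus ACKR2KO. Fibroblast and matrix genes had a median of -0.16 (adjusted p = 0.0401, 0.773 with an estimated correlation), with Postn at -2.12 ± 0.24 and Lum at -1.27 ± 0.20, and that median was 0.25 without the WT arrays and 0.52 without the ACKR2KO_ApcMin arrays. The calls of the fibroblast, helper T cell and chemokine receptor lists held in 1, 3 and 4 of 6 alternative settings, and those of the interferon, enterocyte, and enteric neuron and glia lists in 5 of 6.

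The lists that did not pass in small-intestinal tumours were ACKR2 ligands (adjusted p = 0.952, with Ccl8 falling by 1.48), cytotoxic T and NK cells (0.952, with Cd2 rising by 1.41), macrophages (0.952), neutrophils (0.584), the leukotriene pathway (0.752) and inflammatory cytokines (0.475). MHC class II reached 0.752, colonocytes 0.0636, goblet cells 0.101, Paneth cells 0.051, enteroendocrine cells 0.105, tuft cells 0.788 and endothelium 0.169. Exocrine pancreas reached 0.952, with Pnliprp1 rising by 2.13, the red blood cell gene Alas2 0.334 and the early stress response 0.952, with Hspa1b rising by 0.82. In all, 382 genes rose and 165 fell. Genes at least 2-fold apart in both small-intestinal pairs numbered 441 higher and 159 lower, where independent lists would share 50.2 and 18.4. With any single array left out, limma called 0 genes (1240 to 3016 at an unadjusted p under 0.05).

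**Figure D2:**
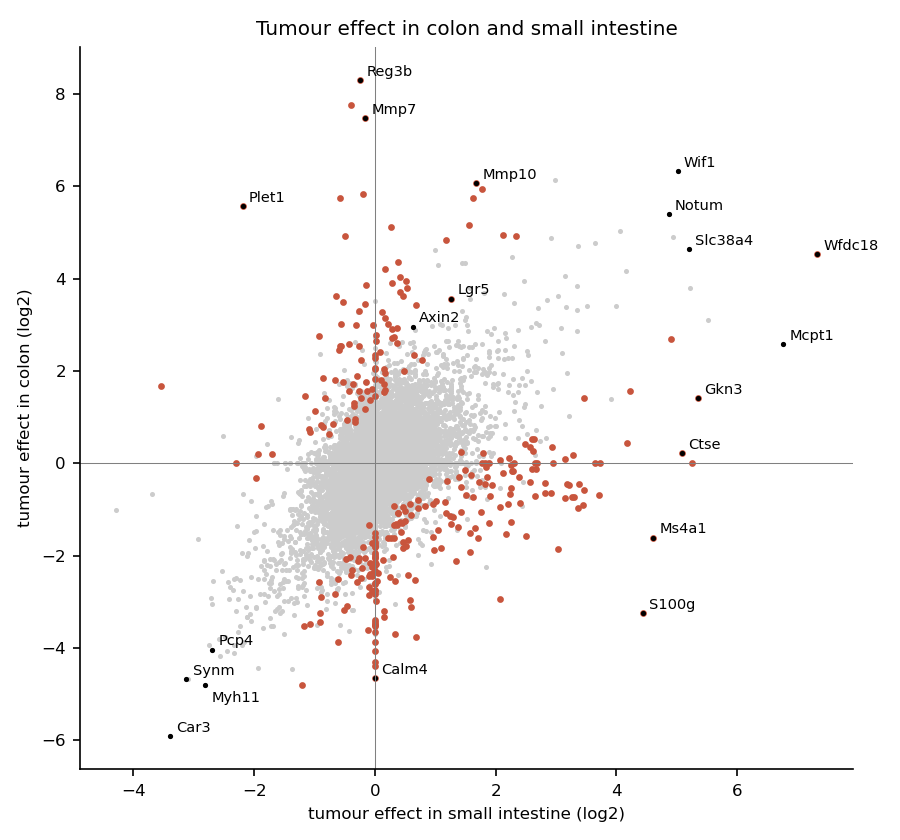
Tumour effect of each of the 14027 genes in colon (vertical axis) against small intestine (horizontal axis), both as log2 differences from the limma model; 301 genes in red differed between the tissues at an adjusted p under 0.05. Wif1 and Notum lie high on both axes, Reg3b and Mmp7 on the colon axis alone, and Mcpt1 lies further along the small-intestine axis.

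The tumour effect was compared between the tissues to ask where colon and small-intestinal tumours part. It was larger in colon for Paneth cell genes by 6.33 (median of the difference, camera adjusted p = 7.82e-11, 0.442 with an estimated correlation), for proliferation genes by 1.15 (2.15e-12, 0.544 with an estimated correlation) and for neutrophil genes by 2.79 (6.91e-06, 0.442 with an estimated correlation). B and plasma cell genes (-2.13, adjusted p = 1.32e-05, 0.599 with an estimated correlation) and mast cell genes (-1.75, 0.00025, 0.442 with an estimated correlation) rose more in small intestine. ACKR2 ligands differed by 0.95 (0.00802, 0.442 with an estimated correlation). In all, the effect was higher in colon for 99 genes and lower for 202. With any single array left out, limma called 0 genes (1355 to 2934 at an unadjusted p under 0.05).

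ACKR2KO_ApcMin tumours were compared with ApcMin tumours to ask what loss of ACKR2 changes in tumours, the comparison named in the title of the series. Xist, the intermediate filament gene Synm, the phosphoglucomutase-related muscle gene Pgm5 and the potassium channel regulator gene Abcc9 fell in both tissues, and 0 genes rose. Xist was at -5.25 ± 0.15 (adjusted p = 0.000438), which moved with the sex markers of the pools, and Synm, Pgm5 and Abcc9 at -3.41 ± 0.27, -2.47 ± 0.19 and -2.11 ± 0.17 (adjusted p = 0.0469 each). All 10 smooth muscle genes were lower in both pairs and 1, Synm, passed over all genes (10 fell adjusted over the list alone). The list median was -1.97 (camera adjusted p = 2.51e-10, 0.681 with an estimated correlation), and Actg2, Myl9 and Myh11 were at -2.71 ± 0.42, -1.86 ± 0.22 and -2.87 ± 0.61 (adjusted p = 0.134, 0.0926 and 0.165). Fibroblast and matrix genes had negative differences in 15 of 15 cases (0 passed over all genes, 11 fell adjusted over the list alone), with a median of -1.11 (adjusted p = 2.44e-09, 0.681 with an estimated correlation) and Col1a1 at -2.20 ± 0.22 (adjusted p = 0.0926). Endothelial genes were lower in 9 of 9 cases (7 fell adjusted over the list alone), with a median of -0.87 (adjusted p = 2.88e-05, 0.681 with an estimated correlation). Enteric neuron and glia genes had a median of -0.44 (-0.93 to -0.24 over 5 alternative settings; 3 fell adjusted over the list alone; adjusted p = 0.0127, 0.681 with an estimated correlation), with the neuropeptide gene Vip at -3.08 ± 0.37 (adjusted p = 0.0926).

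Mast cell and interferon genes were higher in ACKR2KO_ApcMin than in ApcMin tumours as lists, while no single member passed over all genes. The Actb 3'/5' ratio moved with the same groups, at 1.39 and 1.32 in the ACKR2KO_ApcMin and 1.14 and 1.13 in the ApcMin tumours of colon and small intestine. Mast cell genes had a median of 0.51 (0.38 to 1.29 over 5 alternative settings; adjusted p = 0.000906, 0.681 with an estimated correlation), and 6 of 12 rose adjusted over the list alone. Mcpt1 differed by 3.03 ± 0.91 (adjusted p = 0.235), Mcpt2 by 2.43 ± 0.59 (0.184), Cma1 by 1.32 ± 0.25 (0.154) and Cpa3 by 1.29 ± 0.35 (0.207). In colon tumours the Mcpt1 signal was 2316 in the ACKR2KO_ApcMin pool and 49.9 in the ApcMin pool, at least 36.1-fold higher. In small-intestinal tumours it was 14040 and 7561. Interferon response genes had positive differences in 19 of 19 cases (8 rose adjusted over the list alone), with a median of 0.75 (adjusted p = 9.68e-10, 0.681 with an estimated correlation). Usp18 was at 1.87 ± 0.24 (adjusted p = 0.095), Ifit1 at 1.89 ± 0.37 (0.154) and Oasl2 at 1.30 ± 0.15 (0.0926). Exocrine pancreas genes had a median of 0.83 (2 of 6 rose adjusted over the list alone; adjusted p = 0.00596, 0.681 with an estimated correlation), with medians of 0.07 in the colon pair and 1.23 in the small-intestinal pair, and Pnliprp1 at 1.39 ± 0.27 (0.158). Small-intestinal enterocyte genes had a median of 0.39 (1 of 22 rose adjusted over the list alone; adjusted p = 0.00559, 0.828 with an estimated correlation), with medians of -0.18 and 0.95 in these pairs. The calls of the enterocyte and the enteric neuron and glia lists held in 4 of 5 alternative settings.

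Genes of T cells, chemokines and leukotriene signalling did not pass over all genes between the tumour genotypes. Cd8a differed by 0.41 ± 0.34 (adjusted p = 0.588), Gzmb by 0.17 ± 0.28 (0.803), Ltb4r1 by 0.20 ± 0.21 (0.677), Alox5 by 0.31 ± 0.49 (0.796) and the ACKR2 ligand gene Ccl2 by 0.38 ± 0.20 (0.415). Gzmb, Ltb4r1 and Alox5 were higher in 1 of 2 pairs. Lgr5 differed by 0.61 ± 0.27 (0.346) and Axin2 by -0.34 ± 0.36 (0.685, lower in 1 of 2 pairs), and 1 of 4 other probe sets of Cd8a went the opposite way. List medians that did not pass were 0.01 for ACKR2 ligands (adjusted p = 0.385), 0.22 for other chemokines (0.243), -0.18 for chemokine receptors (0.175), 0.19 for cytotoxic T and NK cells (0.286) and 0.09 for helper and regulatory T cells (0.536). They were -0.23 for B and plasma cells (0.6), 0.01 for macrophages (0.764), -0.49 for neutrophils (0.286), 0.18 for the leukotriene pathway (0.68), 0.08 for inflammatory cytokines (0.538) and -0.06 for MHC class II (0.847). Epithelial lists gave -0.02 for Wnt targets and stem cells (0.68), -0.08 for proliferation (0.438), -0.13 for colonocytes (0.764), 0.13 for goblet cells (0.438), 0.13 for Paneth cells (0.286), 0.14 for enteroendocrine cells (0.385) and 0.29 for tuft cells (0.408). Adipocytes gave 1.05 (0.0717), the red blood cell gene Alas2 -0.24 (0.764) and the early stress response -0.22 (0.764). Adjusted over the list alone, 1 other chemokine rose and 1 fell, 1 proliferation gene fell, and 2 early stress genes rose and 2 fell. The camera test pointed upward against the sign of the median for MHC class II, Wnt targets, colonocytes and the early stress response. Several medians near 0 joined pairs that went opposite ways, which carry no test. They were 0.45 in colon and -0.45 in small intestine for Wnt targets and stem cells, 0.21 and -0.29 for proliferation, -0.67 and 0.40 for colonocytes, -0.20 and 0.44 for goblet cells, -0.42 and 0.39 for MHC class II, and -0.76 and 0.16 for B and plasma cells. Cytotoxic T and NK cell genes were at -0.03 and 0.50 (percentiles 38.0 and 100 among random lists). The leukotriene pathway was at -0.11 and 0.30 (percentiles 26.3 and 97.9). Without tumours, ACKR2KO minus WT gave cytotoxic medians of 0.0 in colon and 0.56 in small intestine.

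Among genes 2-fold in both tissues, ACKR2 effect in tumours, 29 were higher and 185 lower in ACKR2KO_ApcMin, where independent lists would share 5.26 and 31.4. After quantile normalization these were 45 and 105, and after median centring 44 and 116. Those higher included Ubd, Nwd1, Klhl28, Wdfy1 and Usp18, and those lower Vip, Pigt, Grem1, Col1a1, Eml2 and Plvap. Adjusted p-values ran from 0.0503 for Grem1 to 0.175 for Ubd, and 1 of 2 other probe sets of Klhl28 went the opposite way. Within colon tumours Mcpt1, Mcpt2, S100g, Iapp and Ifit1 differed most upward and Xist, Myh11, Cyp2c55, Synm and Actg2 most downward. Within small-intestinal tumours these were Reg1, Car3, Apoc2, Pla2g4c and Mbl2, with log2 differences from 5.32 to 3.54, and Xist, Vip, Synm, Igfbp5 and Crispld2, from -5.25 to -2.78. These single pairs carry no test. Across genes, the differences of the colon and the small-intestinal pair had a Pearson r of 0.282, and genes are not independent replicates. The count of 4 genes was 36 without a floor and 80 among genes above the floor in all arrays; it was 0 with the mean of all probe sets (2237 at an unadjusted p under 0.05 in limma), without the WT arrays (1283) or with any single array left out (1279 to 2027). The call of Pgm5 was lost in 10 of 10 other settings that of Synm in 9 of 10 and that of Abcc9 in 9 of 11.

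**Figure D3:**
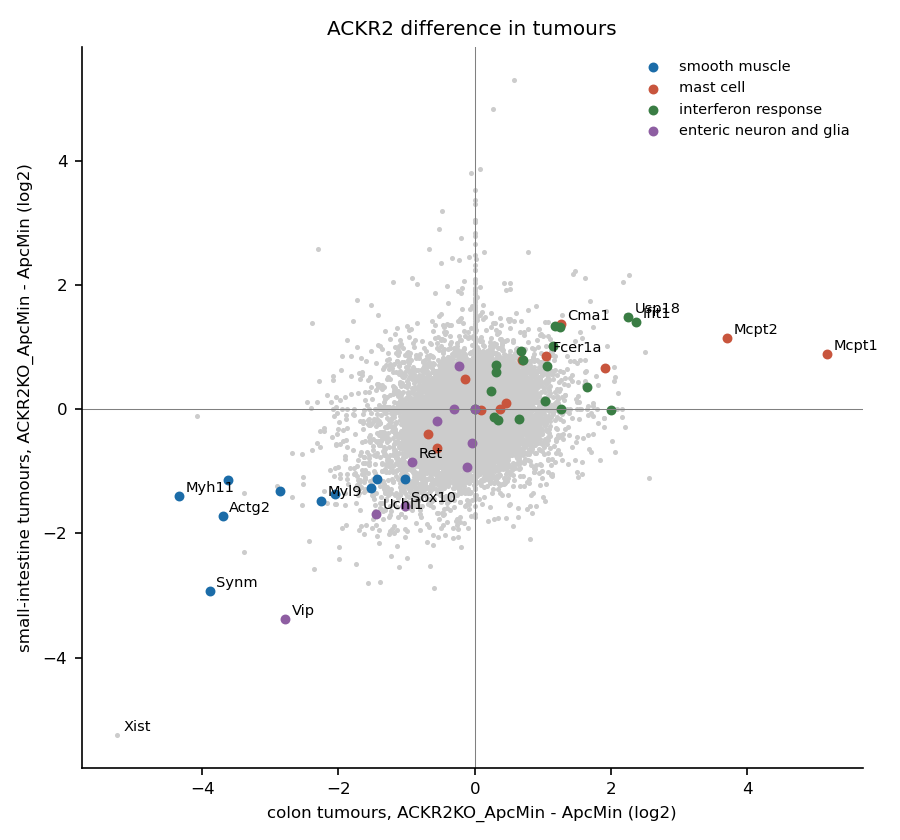
Log2 difference between ACKR2KO_ApcMin and ApcMin tumours for each gene, colon on the horizontal and small intestine on the vertical axis, with 4 gene lists in colour. All 10 smooth muscle genes lie below 0 on both axes and Mcpt1 lies furthest along the colon axis among mast cell genes.

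ACKR2KO tissue was compared with WT tissue to ask what loss of ACKR2 changes without tumours. The Y-linked genes Eif2s3y and Kdm5d rose by 3.82 ± 0.21 and 2.36 ± 0.26 (adjusted p = 0.0189 and 0.0443) from WT values at the floor, which moved with the sex markers of the pools. The glucocorticoid-induced gene Tsc22d3 rose by 1.93 ± 0.20 and the glycosyltransferase gene Gcnt1 by 1.81 ± 0.19 (adjusted p = 0.0407 each), and Diras1 and Snrnp40 also rose. The nuclear RNA Malat1 (-3.32 ± 0.28), the E3 ligase gene Neurl3 (-2.64 ± 0.24) and the collagen gene Col1a1 (-2.23 ± 0.22) fell (adjusted p = 0.0407 each), as did Lrp5, a Wnt co-receptor gene (-3.13 ± 0.37, adjusted p = 0.0455), Zbed6, Mau2, Fbxl18 and Srp54b. The calls of Diras1 and Srp54b were lost in 7 of 10 other settings, those of Zbed6 and Fbxl18 in 6 of 10, that of Kdm5d in 5 of 9 and that of Malat1 in 3 of 11. At 1 of 3 other probe sets of Tsc22d3 and the 1 other of Snrnp40 the direction was the opposite. H2-Ea, Sgk1, Ly6m, Inmt, Retnlb and Cd79a did not pass, with adjusted p-values from 0.0537 to 0.13. In all, 18 genes rose and 62 fell.

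Interferon response genes were also higher as a list in ACKR2KO than in WT tissue, with a median of 0.60 (0 of 19 passed over all genes, 10 rose adjusted over the list alone; camera adjusted p = 0.000697, 0.949 with an estimated correlation). Ifit1 was at 1.75 ± 0.37 (adjusted p = 0.0693) and Usp18 at 1.27 ± 0.24 (0.0604). Lower medians were found for B and plasma cells (-0.75, adjusted p = 0.00723, 0.949 with an estimated correlation; 7 fell adjusted over the list alone), fibroblasts and matrix (-0.74, 0.0159, 0.949 with an estimated correlation; 7 fell and 1 rose adjusted over the list alone) and endothelium (-0.62, 0.0237, 0.949 with an estimated correlation; 0 passed). The endothelial call held in 1 and the fibroblast call in 4 of 5 alternative settings. Cd22 was at -1.94 ± 0.30 and Cd79b at -1.60 ± 0.38 (adjusted p = 0.0537 and 0.0811). Mast cell genes, of which 4 of 12 were above the floor in all non-tumour arrays, had a median of 0 (adjusted p = 0.874), with Mcpt1 at -0.48 ± 0.91, Mcpt2 at 0.45 ± 0.59 and Cpa3 at 0.62 ± 0.35 (adjusted p = 0.795, 0.679 and 0.334). Smooth muscle genes had a median of -0.16 (adjusted p = 0.654), and Wnt target and stem cell genes -0.32 (0.101), with Axin2 at -1.90 ± 0.36 (0.0604). Heat shock gene Hspa1b of the early stress response rose by 1.15 ± 0.14 (adjusted p = 0.0455), and that list did not pass (0.654). The other 21 lists had adjusted p-values from 0.0925 for chemokine receptors to 0.978 for colonocytes.

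Among genes at least 2-fold apart in both non-tumour pairs, 52 were higher and 307 lower in ACKR2KO, where independent lists would share 4.36 and 47.7. The 18 and 62 genes of the ACKR2 effect in non-tumour tissue became 314 and 178 with median centring, and 20 genes in all with quantile normalization. Without a floor 431 genes were called, and 0 without the filter (3099 at an unadjusted p under 0.05 in limma), without the ACKR2KO_ApcMin arrays (3396) or with any single array left out (1332 to 3414).

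The ACKR2 effect was compared between tumour and non-tumour tissue to ask whether it depends on tumour status. Xist was the single gene that differed, and across genes the effects in tumours and in non-tumour tissue had a Pearson r of 0.468, where genes are not independent replicates. Smooth muscle genes differed as a list by -1.88, the median of the difference of effects (camera adjusted p = 4.85e-10, 0.831 with an estimated correlation). At an unadjusted p under 0.05 limma gave 531 genes higher and 588 lower.

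**Figure D4:**
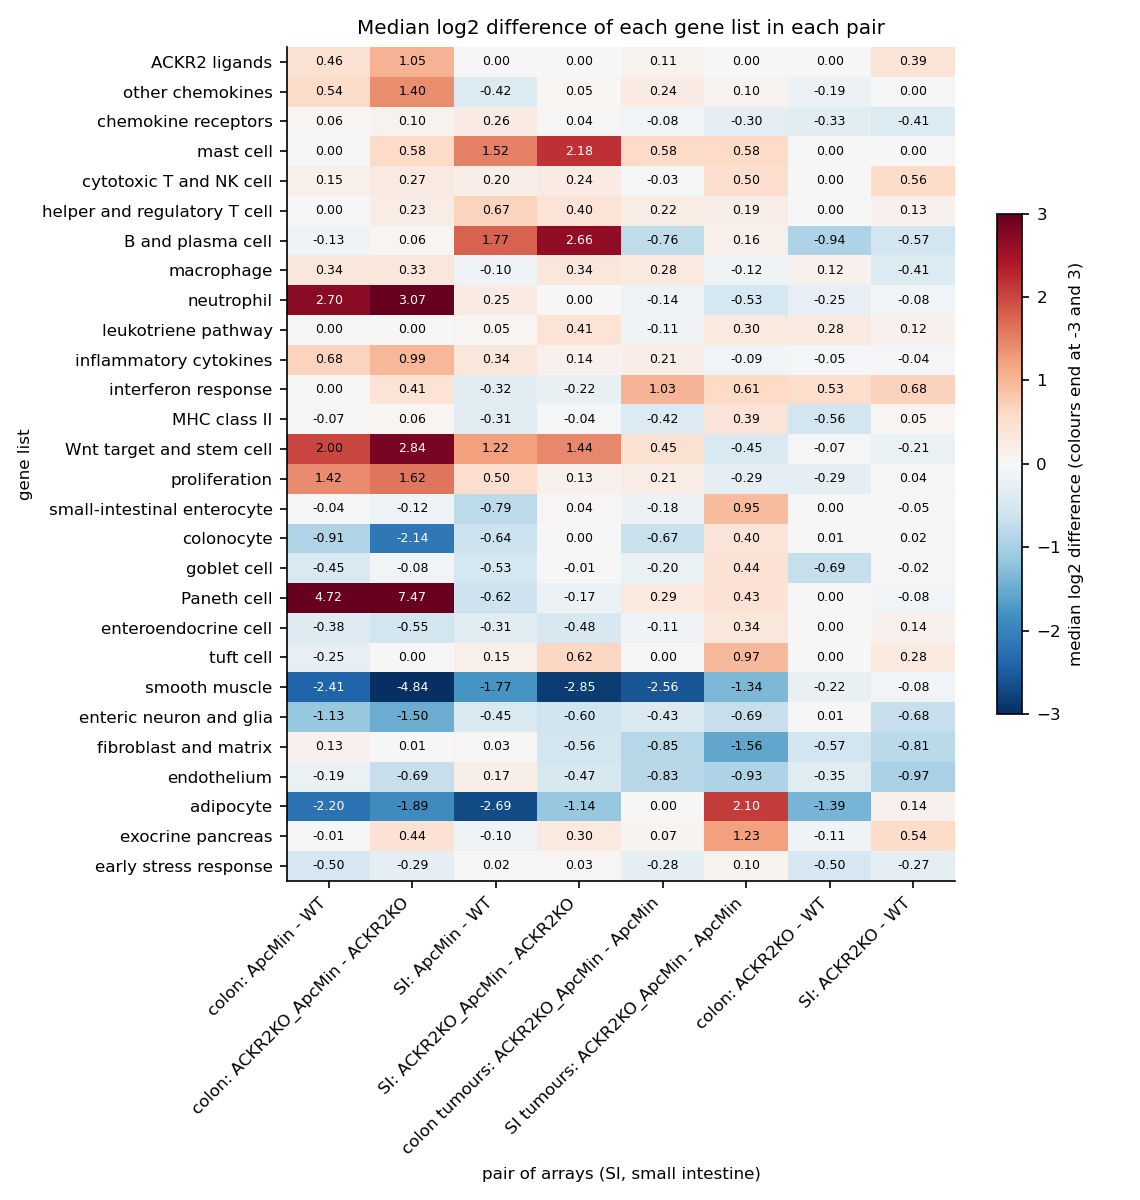
Median log2 difference of the measured genes of each of 28 lists (vertical axis) in each of the 8 pairs of arrays (horizontal axis); colours end at -3 and 3. Smooth muscle is at -1.77 or lower in all 4 tumour pairs, Paneth cell genes are at 4.72 and 7.47 in the colon tumour pairs and below 0 in the small-intestinal ones, and mast cell genes are at 1.52 and 2.18 in the small-intestinal tumour pairs.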

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

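The tests of a smaller muscle wall, of the intensity distribution for smooth muscle and mast cell genes, of smooth muscle genes in non-tumour tissue, of mast cell against other leukocyte genes, and of the 35 splits were chosen after the results were seen; those of genes lower in ACKR2KO tissue and of mast cell genes in non-tumour tissue were written before.

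The tumour effect differed between colon and small intestine for 301 genes, which set these results apart for a closer look, because an average over both tissues hides them. List medians of that difference, colon minus small intestine, were 6.33 for Paneth cells, 2.79 for neutrophils, 1.15 for proliferation, 0.95 for ACKR2 ligands, 0.82 for other chemokines, 0.78 for the interferon response, 0.77 for Wnt targets and stem cells and 0.38 for inflammatory cytokines. They were -0.90 for enteric neurons and glia, -1.31 for smooth muscle, -1.75 for mast cells and -2.13 for B and plasma cells. Camera adjusted p-values of these lists ran from 2.15e-12 for proliferation to 0.0341 for enteric neurons and glia, and with an estimated correlation 0 of them passed (lowest adjusted p = 0.442).

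Named genes with a higher tumour effect in colon than in small intestine were Reg3b (8.55), Reg3g (8.16), Plet1 (7.76), Mmp7 (7.63), Itln1 (6.33), Clca4b (6.03), Mmp10 (4.38), Mmp13 (4.13), Pnliprp2 (4.03), S100a9 (3.98), Cxcl9 (3.69), Cxcl2 (3.66), Il1b (3.16), Pnliprp1 (2.81), Mmp9 (2.79), Il23a (2.77), Lgr5 (2.30), Cxcl3 (2.29), Birc5 (1.78), Lyz1 (1.66), Rrm2 (1.46) and Lyz2 (1.40), as differences of log2 effects. The difference of Kcnip2 (2.30) came from a fall in small intestine. Genes with a lower effect in colon, through a rise in small intestine, a fall in colon or both, were Fcer1a (-2.12), Cma1 (-2.43), Cxcr5 (-2.45), Cxcr4 (-2.58), Wfdc18 (-2.79), Ccr6 (-3.25), Cd79a (-3.36), Atp12a (-3.44), AI854703 (-3.49), Mptx1 (-3.61), Cd22 (-3.69), Cr2 (-3.83), Krt1 (-3.87), Cd79b (-3.89), Gkn3 (-3.93), Cxcl13 (-4.05), Tnnc2 (-4.29), Cyp2d12 (-4.39), Calm4 (-4.65), Ctse (-4.86), Ms4a1 (-6.22) and S100g (-7.69).

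The ACKR2 effect differed between tumours and non-tumour tissue for 1 gene, Xist. List medians of that difference, tumour minus non-tumour, were 1.61 for adipocytes, 0.64 for B and plasma cells, 0.47 for mast cells, 0.38 for Wnt targets and stem cells, -0.40 for fibroblasts and matrix and -1.88 for smooth muscle. Of 12 mast cell genes, 4 were above the floor in all non-tumour arrays, so the floor limited their non-tumour differences and the mast cell value does not show a dependence on tumour status. With an estimated correlation 0 of them passed (lowest adjusted p = 0.831).

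The control probe set for the middle of 18S ribosomal RNA had a signal of 378 in the ApcMin colon tumour array and 312 in the ApcMin small-intestinal tumour array, against 83 and 167 in the ACKR2KO_ApcMin colon and small-intestinal tumour arrays and at most 134 in the non-tumour arrays.

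Smooth muscle genes were lower in ACKR2KO_ApcMin than in ApcMin tumours, by a median of -1.97 (adjusted p = 0.681 with an estimated correlation). Less muscle wall in the sampled tissue might lower them, and the enteric neuron and glia genes of that wall were lower too, by -0.44 (-0.93 to -0.24 over 5 alternatives). That call was lost with the mean of all probe sets (camera adjusted p = 0.0733, and 0.000842 to 0.0733 over 5 alternatives) and with an estimated correlation (adjusted p = 0.681). In ACKR2KO against WT non-tumour tissue the neuron and glia median was -0.39 (camera adjusted p = 0.457), while smooth muscle genes were at -0.16. The neuron and glia genes therefore do not decide whether the muscle wall was smaller in these tumours. A shift of the intensity distribution was excluded by a smooth muscle median of -1.98 after quantile normalization (camera adjusted p = 2.6e-12, and 2.6e-12 to 9.38e-07 over 5 alternatives). In non-tumour tissue the smooth muscle median was -0.16, and 10 of 10 genes were less reduced there than in tumours (exact two-sided signed-rank p = 0.00195). This does not exclude an effect of sex, because the sex markers changed by unlike amounts in the pairs compared. In colon, Xist fell from 9809 to 4522 between WT and ACKR2KO tissue, and from 2954 to 77.9 between ApcMin and ACKR2KO_ApcMin tumours. The smooth muscle genes are not independent replicates, and RNA quality, which moved with the same groups, was not tested for them.

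Mast cell genes were higher in ACKR2KO_ApcMin than in ApcMin tumours, by a median of 0.51 (adjusted p = 0.681 with an estimated correlation). Less muscle and stroma could raise all other cells alike, yet the median of 54 other leukocyte genes was -0.02. The mast cell median lay 0.53 above it (permutation of genes, two-sided p = 0.00381). This p-value does not decide the question, because the mast cell list was compared after it was seen to rise and genes are not independent replicates. After quantile normalization the mast cell median was 0.76 (camera adjusted p = 0.000296, and 0.000296 to 0.00867 over 5 alternatives), so a shift of the distribution was excluded. Whether sex might play a part stayed open: 4 mast cell genes were above the floor in all non-tumour arrays, fewer than the 5 set for that test, and their median was -0.17 there and -0.185 in tumours, where they did not show the pattern either. RNA quality was not tested for them.

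The 62 genes lower in ACKR2KO than in WT non-tumour tissue had a median of -1.83 (median standard error 0.21). After quantile normalization it was -1.62 (0.20) and 15 of 62 calls were kept, while median centring kept 62 of 62. The size that remained argued against a shift of the intensity distribution as the whole cause, but it stayed open because most calls were lost after quantile normalization. In tumours, where the Actb ratio was also higher with ACKR2 loss though by other amounts, the median was -0.81, and lower RNA quality stayed open. The interval of that median, -1.01 to -0.65, came from resampling the 62 genes and holds no variation between arrays or animals. Between ApcMin tumours and WT tissue the median was -0.86, but these genes were chosen as low against the same WT arrays, so sex was left untested: the WT pools alone lacked Y-linked signal.

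The averaged tumour effect was also set beside all 35 splits of the arrays into 4 and 4. For this count a smaller model was used, with the split and the tissue alone, and it called 905 genes for tumour against non-tumour. As many were called in 2 splits, the real one and the split by tissue with 1213, so the share of splits alone cannot exclude chance. The split by tissue, however, follows a real difference between the arrays and was fitted without a separate tissue term. Every remaining split gave at most 1. Those splits mixed tumour with non-tumour arrays, so the tumour difference stayed in their residual spread and low counts were favoured in advance. These counts therefore do not decide whether chance played a part.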

How the results depend on the processing

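Settings without Xist and chromosome Y genes, without both WT or both ACKR2KO_ApcMin arrays, with 1 ACKR2 effect for all arrays, and median centring of lists were chosen after the results were seen. Precision is limited by the number of arrays: leaving out any 1 of 8 left 1 residual degree of freedom, and limma then called 0 genes in every contrast but colon against small intestine (0 to 62, 62 without the ACKR2KO_ApcMin colon tumour array). No paired analysis was possible because each pool had its own label and no number shared with another.

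Counts of called genes moved as follows. The tumour effect in colon (3316) fell to 90 with no filter, and the tumour effect in small intestine (547) to 335 with the floor at the 60th percentile and 29 with no filter. The tumour effect averaged over both tissues (3509) fell to 190 with no filter and 1609 in the additive model. All of these, and the tumour effect in colon minus tumour effect in small intestine, were 0 without both WT arrays or without both ACKR2KO_ApcMin arrays. That difference (301) was 24 with no filter, 160 with the mean of all probe sets and 197 with no trend. The contrast of colon against small intestine in non-tumour tissue (2987) was 262 with no filter, 0 without both WT and 66 without both ACKR2KO_ApcMin arrays.

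The ACKR2 effect in tumours (4) was 36 with no floor, 1 with the floor at the 25th or 60th percentile, 2 with no filter, 80 with a filter on all 8 arrays, and 1 with quantile normalization, median centring or no trend. It was 0 with the mean of all probe sets (2237 at an unadjusted p under 0.05 in limma), without Xist and chromosome Y genes (2183) or without both WT arrays (1283). The ACKR2 effect in non-tumour tissue (80) was 431 with no floor, 52 with the floor at the 60th percentile, 845 with a filter on all arrays, 20 with quantile normalization, 492 with median centring, 1 with the mean of all probe sets or no trend, and 0 with no filter (3099, prior degrees of freedom 0.76) or without both ACKR2KO_ApcMin arrays (3396). Their difference (1) was 2 with no floor or the floor at the 25th percentile, and 0 with the floor at the 60th percentile (859), the mean of all probe sets (1187), no trend (1135) or without Xist and chromosome Y genes (1117). The cause of these changes was not tested.

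Genes called 2-fold in both tissues, ACKR2 effect in tumours (214), numbered 393 with no floor, 106 with the floor at the 60th percentile, 120 with the mean of all probe sets and 31 with a threshold of 1.5. Those 2-fold in both tissues, ACKR2 effect in non-tumour tissue (359), numbered 551 with no floor, 209 with the floor at the 60th percentile and 82 with the threshold of 1.5. With that floor and that threshold, 145 and 100 were 2-fold in all 4 pairs, tumour effect (274), 1014 and 648 were 2-fold in both pairs, tumour effect in colon (1540), and 323 and 255 were 2-fold in both pairs, tumour effect in small intestine (600).

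With 1 ACKR2 effect for all arrays, and 1 array left out, the tumour effect in colon counted between 95 (without ACKR2KO colon) and 2398 genes (without the ApcMin small-intestinal tumours), the tumour effect in small intestine between 2 (without WT colon) and 158 (without the ACKR2KO_ApcMin colon tumours), and the tumour effect averaged over both tissues between 249 and 2645 (without ACKR2KO colon and the ApcMin colon tumours). All arrays gave 3164, 485 and 3401. The tumour effect in colon minus tumour effect in small intestine counted 4 (without the ACKR2KO_ApcMin small-intestinal tumours) to 83, and colon against small intestine in non-tumour tissue 416 (without ACKR2KO colon) to 2330 (both without the ApcMin colon tumours). The additive model gave no value for the other contrasts.

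Among called lists and genes, directions turned for chemokine receptors in small-intestinal tumours (-0.039 after quantile normalization, adjusted p = 0.16), for fibroblasts and matrix there (0.25 without both WT arrays, adjusted p = 0.935, and 0.52 without both ACKR2KO_ApcMin arrays, 0.404), and for Junb in the averaged tumour effect (0.025 without both WT arrays, 0.919). Median centring moved the median of all genes by 0.12 in the ACKR2 effect in non-tumour tissue, 0.10 in tumours and -0.11 for colon against small intestine, and quantile normalization by 0.14 in the first. Of 8 lists called for the ACKR2 effect in tumours, 7 were kept after quantile normalization, 7 with the mean of all probe sets and 8 with no floor. Of 11 in colon tumours 11, 8 and 9 were kept, of 12 in small-intestinal tumours 7, 11 and 9, and of 4 in non-tumour tissue 3, 2 and 3. Without both WT arrays 7 lists were kept in colon tumours, 10 in small-intestinal tumours and 8 for the ACKR2 effect in tumours, and without both ACKR2KO_ApcMin arrays 6 in colon tumours, 10 in small-intestinal tumours and 3 for non-tumour tissue.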

Other observations

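No test in this part was chosen after a result was seen. The percentages of Y-linked signals and the values of the Apc probe sets were picked after they were seen and carry no test.

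Non-tumour colon and small intestine also differed in immune and stromal genes. MHC class II genes were lower in colon for 6 of 6 measured genes (median -2.47, adjusted p = 1.38e-06) and cytotoxic T and NK cell genes for 10 of 16 (-1.76, 1.14e-08). Fibroblast and matrix genes were higher in colon for 13 of 15 (1.25, adjusted p = 2.23e-06) and smooth muscle genes for 4 of 10 (1.11, 0.00324). With an estimated correlation no list passed in this contrast, at adjusted p-values of at least 0.593.

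Eif2s3y in ACKR2KO tissue had 59.8% of the signal of ACKR2KO_ApcMin tumours in colon and 73.4% in small intestine. ApcMin tumours had 59.2 and 73%, and WT tissue 0.195 and 0.213%. For Kdm5d these were 56.8 and 90.9%, 75.8 and 79.3%, and 3.28 and 2.11%. The 2 other probe sets of Xist had the same direction as the chosen one, and Uty had an adjusted p of 0.089 for ACKR2KO against WT.

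A second Apc probe set had signals of 232 and 325 in WT colon and small intestine and between 13.8 and 64.7 in the other 6 arrays. The probe set chosen for Apc went the opposite way, with 1163 and 1176 in WT colon and small intestine against 1253 to 1725 elsewhere. At the remaining Apc probe sets WT overlapped with the other arrays. Signals were 1385 and 1256 in WT against 1200 to 1769 elsewhere, and 371 and 298 in WT against 224 to 333 elsewhere.

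Of 62 genes lower in ACKR2KO than in WT tissue, 62 had a negative difference for the ACKR2 effect in tumours. In limma, 44 of the 62 had an unadjusted p under 0.05 there, while 1462 of all 14027 genes were lower at that level. The count of 44 does not decide whether the fall is shared, because both effects used the same spread per gene from the same fit. Genes called in non-tumour tissue were thus picked in part for a small spread. Across all genes these effects had a Pearson r of 0.468.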
